A study of Mus musculus with 9 samples.

How the data were processed

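RNA sequencing was carried out on microglia, the resident immune cells of the brain, sorted from the visual cortex of 9 adolescent male C57BL/6 mice. Per the labels' protocols, the mice came from 3 litters and were injected under the skin from postnatal day 4 to postnatal day 9, with saline (5 mice) or with ethanol (4 mice) at 1.8 g per kg in 20% v/v solution, 2 injections a day 2 h apart, for a daily dose of 3.6 g per kg. The brains were perfused, the cortex was homogenised on ice and depleted of myelin, and live cells positive for CD11b with low CD45 were sorted straight into lysis buffer. Each library held the cells of a single mouse, so the spread between mice cannot be told apart from that of sorting and library preparation. The litter of each mouse is not given in the sources used here.

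The authors deposited 1 table of raw counts, whole numbers of reads per gene symbol for 45664 symbols in the 9 libraries, with no normalization. The submitters' processing notes name Trimmomatic 0.32, STAR 2.4.2a, HTSeq 0.6.1 and the mouse build GRCm38.p4. Settings, annotation release, read layout and use of strand are not given in the sources used here, so counts of genes that overlap another gene or its antisense partner, or that share sequence with a close copy, carry an uncertainty that the table cannot resolve. Gene coordinates, biotypes, transcript lengths and GC contents were taken by symbol from GENCODE mouse release M21 on GRCm38, which matched 12408 of the 13067 genes tested (95.0%). No column of the table was left out.

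Library totals ranged from 12816198 to 28859244 counts. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 13067 genes. Libraries were scaled by the trimmed mean of M values (TMM), and levels are given as CPM, counts scaled to a common library size. The test was edgeR's quasi-likelihood F test with robust dispersion estimates (edgeR 4.0.16, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors (SE) were taken from the fold change and its F statistic, and 95% intervals from these with the test's degrees of freedom. The square root of the common dispersion, the coefficient of variation between libraries beyond counting error, was 0.208.

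The comparisons, tests, gene lists and rule for named genes were fixed before the data were examined. Ethanol was compared with saline over all libraries with no covariate. Older mice (postnatal days 35 and 36, 4 mice) were compared with younger mice (days 29 and 30, 5 mice) with ethanol as a covariate, and the interaction of ethanol with age cohort was tested in a fit with both terms. The 23 gene lists held 15 sets of microglial and general functions and 8 sets of markers of other cell types that the sort could have let through. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 23 lists, and again with an estimated correlation and with fry. Recorded measures of the mice and summed CPM of the other cell types' markers were compared with exact two-sided permutation tests of the difference of means, enumerating all 126 splits of the 9 mice (Python 3.11.15, scipy 1.17.1).

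Genes were named by rule. For ethanol these were any genes past the threshold, the 4 smallest p-values in each direction whether or not they passed, and from each of the 15 functional lists the member with the highest mean CPM and the member with the smallest p. For age, only genes past the threshold were to be named. For levels these were the 10 highest genes and the 3 highest members of each list. Predicted genes, Rik genes and pseudogenes were passed over. A few genes that the rule names are not reported here. Any other gene is said to have been chosen after its values were seen.

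Alternatives to these choices were DESeq2 1.42.0, limma-voom with sample weights, size factors of the relative log expression kind (RLE), no count filter, a stricter filter (CPM of at least 5 in at least 4 libraries), a surrogate variable (sva 3.50.0), leaving out each library in turn, age, library-name suffix, number of sorted cells or other-cell markers as covariates, each age cohort alone, and the replicate number as a block. For age they also included age in days, a fit without the ethanol term, and the saline or the ethanol mice alone. Recorded measures were also permuted within age cohorts, and marker levels taken as mean log2(CPM + 1) or over plain library sizes. Further alternatives were added after the data were seen. These were leaving out each library in turn together with an estimated correlation, leaving out saline 1 and ethanol 2, the libraries that stood apart from the rest, and removing from each library a smooth trend of log2 CPM on transcript GC content and length (loess, span 0.3).

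The procedure was tested on simulated data with the means, dispersions and library sizes of the 13067 genes and 200 genes changed by a known fold. For ethanol against saline it called 0 genes when none was changed, 15.5% of the genes changed by 1.5-fold, 67.5% of those changed by 2-fold and 90% of those changed by 4-fold. Of the changed genes with a mean CPM of at least 10, 91.9% were called at 2-fold. For older against younger mice the shares were 20.5%, 66.5% and 90.5%. For the interaction they were 0%, 1% and 66%. A shift of 0.5 on the log2 scale put into the 24 measured genes of the complement and phagocytosis list was found by camera with either correlation. With no shift, camera with the preset correlation still called 1 of 23 lists in the simulated ethanol comparison and 0 with the estimated correlation. Simulated genes varied independently. In the real ethanol comparison the estimated correlation was 0.081 for the complement list, 0.735 for neurons and 0.762 for astrocytes. The simulation therefore does not measure how either camera test behaves on lists whose genes vary together.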

Results

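The series asked whether heavy exposure to ethanol in the first days after birth, a period of fast brain growth, left a mark on the transcriptome of visual cortex microglia in adolescence. Microglia from 5 mice given saline and 4 mice given ethanol were sequenced, 1 library per mouse. The saline mice were 36, 30, 35, 29 and 30 days old (saline 1 to 5) and the ethanol mice 35, 35, 30 and 30 days old (ethanol 1 to 4), so both treatments were present in a younger and an older cohort. Saline libraries held 18476279, 28859244, 20156269, 18016777 and 20919085 counts, and ethanol libraries 12816198, 23723166, 17877881 and 19729159. Between 16835 and 18896 genes had at least 1 count in a library.

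The libraries carried the transcripts of microglia at very high levels in both groups. Cst3, which encodes the protease inhibitor cystatin C, averaged 20366 ± 2150 CPM in saline mice (SD, n = 5) and 20677 ± 1371 CPM in ethanol mice (SD, n = 4). Csf1r, the receptor for the growth factor on which microglia depend, averaged 19384 ± 816 and 19132 ± 859 CPM. The lysosomal protease gene Ctsd averaged 18766 ± 1462 and 19682 ± 2528 CPM. P2ry12, the purinergic receptor of ramified microglia, averaged 8050 ± 959 and 8774 ± 1064 CPM, and the fractalkine receptor gene Cx3cr1 7143 ± 440 and 8146 ± 1213 CPM. Serinc3, Laptm5, Itm2b and Selplg were also among the 10 most abundant genes, with means over the 9 libraries of 8453, 6228, 6106 and 6074 CPM.

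Transcripts of other cell types were present at low levels. Summed over each list, astrocyte markers reached 385 ± 96.8 CPM in saline and 452 ± 71.5 CPM in ethanol mice, most of it from Slc1a3, a glutamate transporter gene that microglia also express (275 ± 28.8 and 287 ± 33.0 CPM), and neuronal markers 49.2 ± 25.7 and 55.3 ± 29.9 CPM. Oligodendrocyte markers, mostly Cnp and Mbp, reached 222 ± 25.2 and 240 ± 16.1 CPM. Markers of border macrophages reached 67.1 ± 12.1 and 53.7 ± 25.7 CPM, nearly all from Mrc1, the mannose receptor gene. Endothelial and pericyte markers reached 68.7 ± 5.22 and 60.7 ± 8.24 CPM, lymphocyte markers 48.5 ± 3.14 and 55.5 ± 9.98 CPM (nearly all Cd79b), monocyte and neutrophil markers 6.96 ± 1.30 and 8.55 ± 5.15 CPM, and erythroid markers 1.31 ± 0.748 and 1.07 ± 0.468 CPM. None of the 8 sums differed between the groups in exact two-sided permutation tests (adjusted p from 0.483 to 0.754).

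The neuronal and astrocyte transcripts were not spread evenly over the libraries. In saline 1, Kif5a, which encodes a neuronal kinesin motor, was at 1.46 CPM (26 counts, 95% Poisson interval 17.0 to 38.1) against 60.6 to 255 CPM in the other 8 libraries. Slc1a2, the main glutamate transporter of astrocytes, was at 0.504 CPM against 16.6 to 70.6 CPM, and Cpe, which encodes a peptide-processing enzyme of neurons, at 4.26 CPM against 73.1 to 207 CPM. Kif5a, Cpe, Hpcal4 and Clu were chosen after their values were seen. The median of the 21 measured neuronal and astrocyte markers had a log2 deviation of -3.94 from the other libraries. Slc1a3 was at 267 CPM in saline 1 and between 240 and 330 CPM elsewhere. Intervals on counts cover counting error only.

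**Figure D1:**
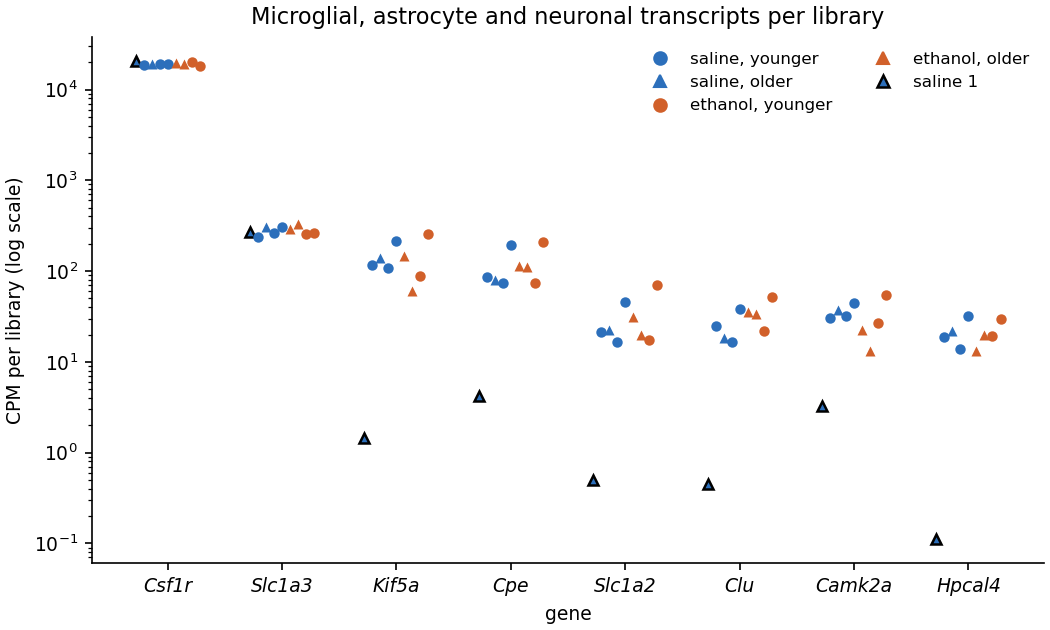
CPM on a log scale for 8 genes in each of the 9 libraries, 1 point per library, coloured by treatment and shaped by age cohort, with saline 1 outlined. Slc1a3 of saline 1 lies among the other libraries, and its Csf1r (20825 CPM) is the highest of the saline mice. Kif5a (1.46 CPM), Cpe (4.26 CPM), Slc1a2 (0.504 CPM), Clu (0.448 CPM), Camk2a (3.30 CPM) and Hpcal4 (0.112 CPM) of saline 1 lie below all other libraries.

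A further library, ethanol 2, had 695 of 8538 well expressed genes more than 2-fold below the libraries other than saline 1, against 1 to 40 such genes in each of the other 8. Tgfb1, which encodes a growth factor that maintains microglial identity, was at 43.0 CPM there against 248 to 288 CPM elsewhere. The transcription regulator gene Ski was at 108 CPM, against a mean of 739 ± 97.2 CPM in the other libraries (SD, n = 8), and the histone demethylase gene Phf2 at 2.73 CPM, against 29.1 ± 1.32 CPM (SD, n = 8). Ski and Phf2 were chosen after their values were seen. The genes that were low there had long transcripts (median 5956 against 3092 nucleotides) with a high GC content (median 53.1% against 49.5%). None of the 20 homeostatic microglia genes was among them, nor any of the 22 genes read from the Toll-like receptor list. With 695 of 8538 genes low, few of 20 would be low by chance, so this does not set the homeostatic list apart. The first principal component of log2 CPM (31.0% of the variance) separated saline 1 from the rest and the second (22.3%) separated ethanol 2.

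**Figure D2:**
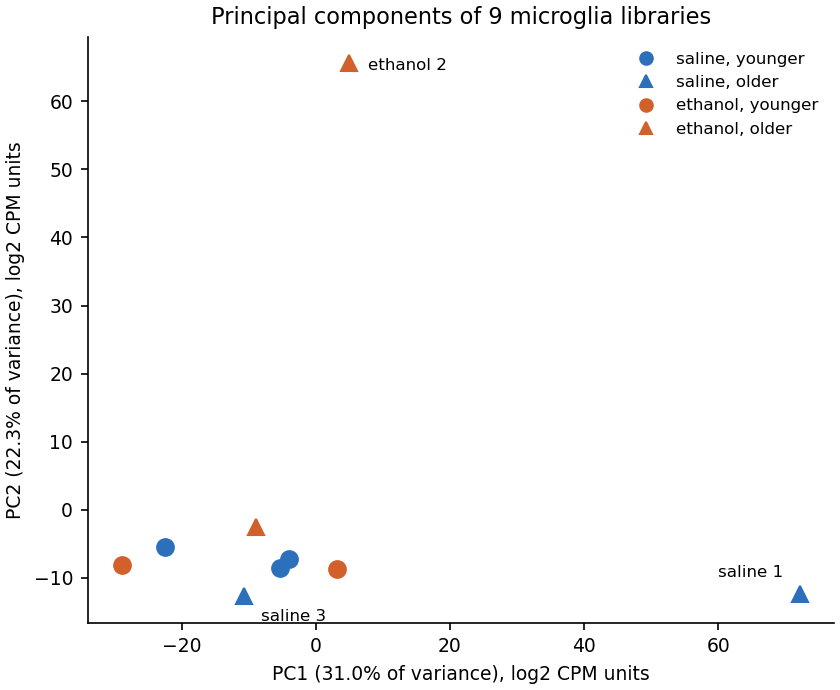
First and second principal components of log2 CPM for the 9 libraries, with colour for treatment and shape for age cohort. Saline 1 lies at 72.1 on the first component and ethanol 2 at 65.6 on the second, and the remaining libraries of both treatments lie together.

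**Figure D3:**
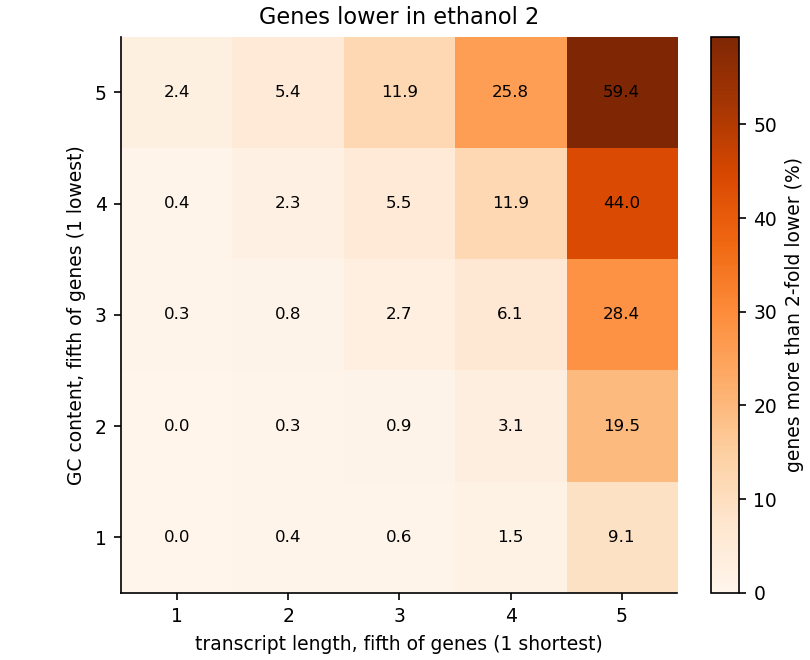
Share of genes more than 2-fold lower in ethanol 2, in percent, for genes divided into 5 equal classes by transcript length and 5 by GC content. The share is 0% among the shortest transcripts of lowest GC content and 59.4% among the longest of highest GC content.

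No difference in the mice or in the yield of cells passed the test. Body weight at collection averaged 17.6 ± 2.66 g in saline mice (SD, n = 5) and 16.7 ± 1.63 g in ethanol mice (SD, n = 4). Dissected tissue weighed 41.0 ± 6.52 and 34.3 ± 14.1 mg, and gave 13878 ± 3619 and 12719 ± 4467 sorted microglia, or 352 ± 125 and 381 ± 49.0 cells per mg. RNA concentration was 201 ± 24.4 and 244 ± 67.1 pg per µl, and the RNA integrity number 9.54 ± 0.410 and 9.53 ± 0.435. The adjusted p of these and of library total and genes detected, from exact two-sided permutation tests over 8 measures, ranged from 0.762 to 1.

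Ethanol against saline was the main comparison. No gene passed the test between the 4 ethanol and the 5 saline mice. Among the genes of resting microglia, Csf1r had a log2 fold change of -0.02 (95% interval -0.15 to 0.11), Cst3 of 0.02 (-0.16 to 0.20) and P2ry12 of 0.12 (-0.10 to 0.35). C1qb, a subunit of the complement protein that tags synapses, had one of 0.07 (-0.12 to 0.27), and B2m, the shared subunit of class I antigen-presenting molecules, one of 0.05 (-0.10 to 0.20).

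In edgeR's quasi-likelihood test 0 of 13067 genes passed, with a smallest adjusted p of 0.963, and 386 genes had an unadjusted p under the threshold where 653 would be given by chance alone (768 genes without ethanol 4). DESeq2 called 0 genes (578 under the unadjusted threshold) and limma-voom 0 (505). The 95% interval of the fold change lay within 2-fold for 10356 genes (79.3%). Among the 8477 genes with a mean CPM of at least 10 it did so for 8279 (97.7%), and 84.4% were within 1.5-fold. Of the 1350 genes below 1 CPM 5.85% had an interval within 2-fold.

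The named genes with the smallest p-values in each direction had log2 fold changes from -0.89 to 0.56, and none passed the threshold. The median absolute log2 fold change of all genes was 0.118. On the higher side stood Trim36, a ubiquitin ligase gene (chromosome 18, 46165300 to 46212607, GRCm38), at 85.1 ± 4.52 CPM in saline and 107 ± 3.65 CPM in ethanol mice, a log2 fold change of 0.33 ± 0.07 (SE), and the zinc finger gene Zfp449 (X, 56346400 to 56365674), with a log2 fold change of 0.56 ± 0.13. Rcc1, the exchange factor for the nuclear transport GTPase Ran, and Ppap2a, a lipid phosphatase gene, had log2 fold changes of 0.36 ± 0.09 and 0.36 ± 0.10. On the lower side stood Homer1, a scaffold protein gene (chromosome 13, 93299635 to 93405129), at 10.4 ± 2.58 and 5.61 ± 1.06 CPM, a log2 fold change of -0.89 ± 0.21, and Dusp6, a phosphatase gene that limits ERK signalling (chromosome 10, 99263231 to 99267489), at 847 ± 229 and 531 ± 49.8 CPM, a log2 fold change of -0.67 ± 0.17. The deacetylase gene Hdac6 and the co-chaperone gene Dnajb2 had log2 fold changes of -0.47 ± 0.12 and -0.38 ± 0.11. All 8 had an adjusted p of 0.963.

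**Figure D4:**
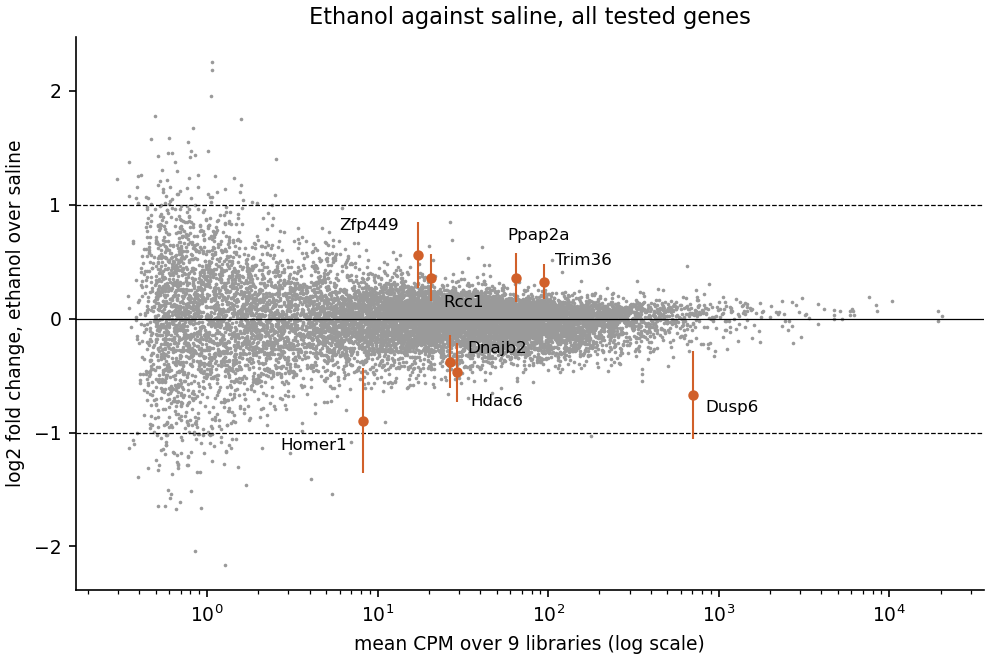
Log2 fold change of ethanol over saline against mean CPM on a log scale for the 13067 genes tested, 1 grey point per gene. Orange points with 95% intervals mark the 8 genes of smallest p, from Homer1 at -0.89 to Zfp449 at 0.56; none passed the threshold, and dashed lines mark 2-fold.

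Inflammatory genes were of particular interest for an exposure to ethanol. The list of cytokines, chemokines and inflammatory mediators had 14 of 19 measured members below 0, with a median log2 fold change of -0.20, and passed camera's test with the preset correlation (adjusted p = 0.0251) but not with an estimated correlation (adjusted p = 0.615). Il6, the interleukin with the smallest p of the list, averaged 7.37 ± 0.827 CPM in saline and 5.09 ± 1.17 CPM in ethanol mice, a log2 fold change of -0.52 ± 0.19. Icam1, an adhesion molecule gene, had one of 0.13 ± 0.09, and Nfkbia, the NF-kappaB inhibitor gene, one of 0.41 ± 0.21, against the direction of the list. Nlrp3, the inflammasome sensor gene, chosen after its values were seen, had one of -0.61 ± 0.24, and was lowest in ethanol 2 (23.1 CPM, others 35.9 to 80.6 CPM). Tgfb1, at -0.38 ± 0.40, was low in ethanol 2 alone. The list lost its call without saline 1 (adjusted p = 0.232), ethanol 1 (0.144) or ethanol 4 (0.203), with a median log2 fold change of -0.15, -0.08 and -0.17 and a mean of -0.16, -0.16 and -0.20 there, against a mean of -0.22 over all mice. Without saline 2 the median was -0.13.

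The marker lists of other cells accounted for the remaining calls. All 12 measured astrocyte markers were above 0, with a median log2 fold change of 0.68 (camera, adjusted p = 0.00050; adjusted p = 0.615 with an estimated correlation), as were 8 of 9 neuronal markers, with a median of 0.36 (0.00587; adjusted p = 0.644 with an estimated correlation). These are the transcripts nearly missing from saline 1, and without that library neither list passed (0.0689 and 0.424), with medians of 0.37 and 0.09. Neurons also lost the call without ethanol 4 (0.211), where the median was -0.04 and 4 of 9 were above 0, though camera still placed the list on the higher side. The median of neurons was 0.56 without ethanol 1, and that of astrocytes was 0.26 without ethanol 4 and 1.08 without saline 5. All 4 measured border macrophage markers, Mrc1, F13a1, Pf4 and Cbr2, were below 0, with a median of -1.02 (0.00587; adjusted p = 0.549 with an estimated correlation). Without saline 1 all 4 were still below 0, with a median of -0.81 (adjusted p = 0.0532). F13a1, Pf4 and Cbr2 averaged between 0.341 and 1.45 CPM in either group and were highest in saline 1, at 2.52, 0.952 and 1.40 CPM.

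The other 19 lists did not pass. Antigen presentation had 14 of 17 members above 0 (adjusted p = 0.0576), type I interferon response 14 of 20 (0.0878) and homeostatic microglia 14 of 20 (0.128), while 17 of 24 epigenetic regulators were below 0 (0.0878). In the interferon list, Ifit1 averaged 3.47 ± 1.03 and 5.31 ± 1.40 CPM, a log2 fold change of 0.62 ± 0.27, and Irf9 had one of 0.18 ± 0.12. In the list of ethanol metabolism and oxidative stress (0.120), Srxn1, a gene of the antioxidant response, had a log2 fold change of 0.64 ± 0.23 and Ncf1, a subunit of the NADPH oxidase, one of -0.04 ± 0.09. Among the epigenetic regulators, the deacetylase gene Sirt1 had one of 0.36 ± 0.10 and the acetyltransferase gene Ep300 one of -0.27 ± 0.28, the latter at a low level in ethanol 2. Adjusted p was 0.856 for Toll-like receptor signalling (Tirap 0.19 ± 0.08, Irf8 0.01 ± 0.08), 0.726 for disease-associated microglia (Lgals3 -0.77 ± 0.37, Ctsd 0.07 ± 0.09) and 0.732 for complement and phagocytosis (Gas6 0.24 ± 0.08). It was 0.182 for alternative activation (Socs3 -0.44 ± 0.14, Il10ra 0.15 ± 0.12), 0.856 for purinergic, adenosine and adrenergic receptors (Kcnk13 0.24 ± 0.13) and 0.560 for cell cycle (Mcm3 0.03 ± 0.10, Mcm6 -0.23 ± 0.14). It was 0.403 for the immediate early and dissociation response (Egr3 -1.65 ± 0.66 at 0.751 and 0.230 CPM, Rhob -0.25 ± 0.27, the latter lowest in ethanol 2), 0.856 for cholesterol synthesis (Dhcr7 -0.21 ± 0.11, Scd2 -0.07 ± 0.14) and 0.560 for the unfolded protein response (Ppp1r15a 0.41 ± 0.12, Canx 0.09 ± 0.09). H2-DMb1, of the antigen presentation list, had a log2 fold change of 0.20 ± 0.11. The remaining marker lists had adjusted p-values of 0.0934 (oligodendrocytes), 0.120 (endothelial cells and pericytes), 0.511 (monocytes and neutrophils), 0.214 (lymphocytes) and 0.560 (erythroid cells). With an estimated correlation or with fry 0 of the 23 lists passed, and adjusted over the list alone 0 members of any list passed. The mean of the members and the direction of camera differed in sign for Toll-like receptor signalling (mean -0.0032, median 0.01), complement and phagocytosis (mean -0.05, median 0.03) and the immediate early response (mean -0.02, median 0.05), which camera placed on the higher side. Without ethanol 2 the log2 fold change was -0.02 for Rhob, -0.0052 for Ep300, 0.06 for Irf9, 0.10 for H2-DMb1, 0.04 for P2ry12, 0.08 for Icam1, 0.14 for Kcnk13 and -0.12 for Dhcr7. Without ethanol 1 it was -0.49 for Rhob, -0.44 for Ep300, 0.28 for Irf9 and 0.07 for Il10ra. Without saline 3 it was -0.14 for Rhob, 0.08 for Icam1, 0.07 for P2ry12 and 0.02 for B2m. It was 0.09 for Il10ra without saline 1 or saline 2, 0.03 for Canx without saline 2 and 0.05 without ethanol 3. Without ethanol 4 it was 0.08 for B2m and -0.10 for Mcm6.

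Several of these lists passed with the preset correlation when a library was left out. With an estimated correlation, tried on the same 9 fits after the data were seen, 1 of 207 list tests passed, border macrophages on the lower side without ethanol 3 (adjusted p = 0.0484). Antigen presentation passed on the higher side without saline 1 (adjusted p = 0.0128), saline 5 (0.0271), ethanol 1 (0.0155) or ethanol 4 (0.00773). The type I interferon response did so without saline 4 (0.0446), saline 5 (0.0107), ethanol 1 (0.00486) or ethanol 4 (0.0380), and homeostatic microglia without saline 1 (0.0151) or ethanol 4 (0.0260). Oligodendrocyte markers passed on the higher side without saline 2 (0.0468) or saline 5 (0.0271), the immediate early response without ethanol 3 (0.00749) and ethanol metabolism without ethanol 4 (0.0352). On the lower side, epigenetic regulators passed without ethanol 1 (0.0155) or ethanol 4 (0.0431), alternative activation without ethanol 1 (0.0272) or ethanol 3 (0.00112), and endothelial and pericyte markers without ethanol 3 (0.0158). Ethanol 2 had the highest summed CPM of the interferon list (553 CPM) and the lowest of epigenetic regulators (916 CPM). Without ethanol 2 the median log2 fold change was -0.02 for the interferon list (adjusted p = 0.871), -0.03 for epigenetic regulators (0.762), 0.0079 for homeostatic microglia (0.650), 0.04 for antigen presentation (0.394), -0.0080 for ethanol metabolism (0.871, placed by camera on the higher side) and -0.02 for the immediate early response (0.871).

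Age cohort was the second difference between the mice. No gene passed edgeR's test between the 4 older and the 5 younger mice, with 372 genes under the unadjusted threshold where chance gives 653. That number was 691 without saline 3, 197 without ethanol 4, 797 with a surrogate variable and 801 with the replicate number as a block. The older mice had lower levels of neuronal markers, with 8 of 9 below 0 and a median log2 fold change of -0.95 (camera, adjusted p = 2.0e-05), and of astrocyte markers, with 11 of 12 below 0 and a median of -0.92 (0.00044), with an adjusted p of 0.593 for both lists with an estimated correlation. Saline 1, which nearly lacked these transcripts, was the oldest mouse, and without it neither list passed (0.121 and 0.715), with medians of -0.56 and -0.39. The median of neurons was -1.81 without saline 3 and that of astrocytes -0.60 without saline 5. DESeq2 called 1 gene, Ftl2, a ferritin light chain copy, and limma-voom 0 (430 under the unadjusted threshold). Adjusted over the list alone, 1 gene passed, Nfkbia in the list of cytokines (adjusted p = 0.0130), at 97.4 ± 9.28 CPM in younger and 149 ± 34.6 CPM in older mice, a log2 fold change of 0.56 ± 0.12; over all genes its adjusted p was 0.973.

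Lists of microglial and stress genes lay higher in the older mice with camera's preset correlation. The immediate early and dissociation response had 18 of 22 members above 0, with a median log2 fold change of 0.15 (adjusted p = 0.00124; adjusted p = 0.593 with an estimated correlation), and among its members Atf3 had a log2 fold change of 0.71 ± 0.30, Btg2 of 0.33 ± 0.13 and Egr1 of 0.36 ± 0.29. Atf3 was high in saline 1 and ethanol 2 alone (38.3 and 29.7 CPM, others 12.5 to 18.0 CPM), and its log2 fold change was 0.37 without saline 1 and 0.48 without ethanol 2. That of Egr1 was 0.16 without ethanol 2, 0.13 without ethanol 3 and 0.56 without saline 3. The call was lost without ethanol 3 (0.0711), with a median of 0.08, and without saline 1 the median was 0.37. Disease-associated microglia had 15 of 21 members above 0 (median 0.15, adjusted p = 0.00653; adjusted p = 0.593 with an estimated correlation), with Lyz2, the lysozyme gene, at 0.36 ± 0.13 and Igf1, a growth factor gene, at -0.89 ± 0.27, against the list. Ethanol metabolism and oxidative stress had 17 of 23 above 0 (median 0.11, adjusted p = 0.00768; adjusted p = 0.593 with an estimated correlation), with Hmox1, the heme oxygenase gene, at 0.36 ± 0.14 (0.22 without saline 3), and homeostatic microglia 16 of 20 (median 0.07, adjusted p = 0.0297; adjusted p = 0.624 with an estimated correlation), with Cst3 highest in level. Members of these lists outside the levels rule were chosen after their values were seen. Without saline 1 the adjusted p of these 3 lists with the preset correlation was 0.351, 0.0518 and 0.754, with medians of 0.08, 0.06 and 0.02. Disease-associated microglia also missed the threshold without saline 2 (0.0507) or ethanol 2 (0.0531), ethanol metabolism without ethanol 2 (0.101) or ethanol 4 (0.120), and homeostatic microglia without saline 4 (0.0931), saline 5 (0.102), ethanol 2 (0.0653) or ethanol 4 (0.301). The medians there were 0.14 and 0.12, 0.08 and 0.07, and 0.07, 0.06, 0.05 and 0.03. Without saline 3 the median of homeostatic microglia was 0.12. The other 17 lists had adjusted p-values from 0.127 to 0.875. Of these, the unfolded protein response passed on the higher side without saline 3 (0.0118) or ethanol 3 (0.0316), cytokines without saline 3 (0.0366) and complement and phagocytosis without ethanol 3 (0.0340), and on the lower side the type I interferon response without ethanol 2 (0.00010) and oligodendrocyte markers without ethanol 3 (0.0340). With an estimated correlation, again tried after the data were seen, 0 of the 207 list tests for age without 1 library passed (smallest adjusted p = 0.381). The mean differed in sign from camera's direction for antigen presentation (mean -0.12, median 0.06), complement and phagocytosis (mean -0.03), cytokines (mean -0.0049) and purinergic receptors (mean -0.0093), all placed on the higher side, as did the median for endothelial cells and pericytes (-0.04).

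Without saline 1 and ethanol 2, a choice made after the data were seen, 3 genes were higher in the older mice in edgeR's test, and 0 lower. Tagap, a GTPase-activating protein gene of immune cells (chromosome 17, 7926000 to 7934897), had a log2 fold change of 0.93 ± 0.09 (adjusted p = 0.00193), Nfkbia (chromosome 12, 55489410 to 55492647) of 0.73 ± 0.08 (0.00281) and Adrb1, the beta-1 adrenergic receptor gene (chromosome 19, 56722199 to 56733113), of 0.81 ± 0.11 (0.0136). This fit set 2 older mice, both 35 days old, against 5 younger ones. Of the older mice left out, saline 1 had 99.5 CPM of Tagap and 100 CPM of Nfkbia, within the range of the younger mice. Ethanol 2 had 157 and 164 CPM, above that range. Adrb1 was at 38.9 CPM in saline 1 and lowest of all in ethanol 2 (16.2 CPM), against the direction of the fit. Age cohort also overlapped the suffix of the library names: all 4 libraries of one suffix came from mice aged 30 days, the other suffix held the 3 mice aged 35 days and the mouse aged 29 days, and saline 1 had neither. A fit of all 9 libraries with the suffix as a covariate could not decide on Tagap, Nfkbia and Adrb1. In it age rested on a single younger mouse, saline 4, against the 3 mice aged 35 days of the same suffix. The mice came from 3 litters and the litter of each is not given, so age could not be told apart from litter.

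Whether ethanol acted differently in the cohorts was tested by their interaction, on 2 or 3 mice per arm. No gene passed edgeR's test, with 423 under the unadjusted threshold (812 without saline 3, 268 without saline 4 and 2316 without ethanol 1). DESeq2 called 1 gene, the unannotated transcript C130089K02Rik. Leaving out ethanol 1 left ethanol 2 as the single older ethanol mouse. Of the genes that passed in that fit, mostly lower, 70.5% were low in ethanol 2, against 10.6% of all tested genes. Low genes were counted here among all tested genes, a wider set than the well expressed genes described above. Astrocyte markers passed by camera with the preset correlation (12 of 12 above 0, median 1.37, adjusted p = 4.5e-05). So did the immediate early and dissociation response (16 of 22 above 0, median 0.31, adjusted p = 0.00503). Both were placed on the side of a higher ethanol effect in the older mice. Neither passed with an estimated correlation (adjusted p = 0.979 for both). Saline 1 is 1 of the 2 older saline mice, and without it saline 3 alone stood for them. Both lists stayed on the higher side in that fit. The astrocyte list no longer passed there, but with a single mouse in an arm, calls gained or lost decide nothing. Among the lists that did not pass, median or mean differed in sign from camera's direction for antigen presentation (median -0.08), complement and phagocytosis (median -0.01), neurons (median -0.0055), cell cycle (mean -0.20) and the unfolded protein response (mean 0.0070).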

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

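All tests in this part of what lies behind a pattern were chosen only after the pattern had been seen. The distance of the highest or lowest mouse of a group from its nearest neighbour was set against the range of the group for 246 sets of values. In 25 of them the distance passed Dixon's 95% limit, where chance alone gives about 12. The sets came from the same mice and held list sums along with their own members. They are not independent, so 25 against 12 cannot be read as an excess. Of these, 10 were in saline 1 and 2 in ethanol 2.

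Saline 1 had the highest value of the saline mice for the summed CPM of homeostatic microglia genes (123274, others at most 110522), of complement and phagocytosis genes (35539) and of the unfolded protein response (7966). It was also highest for Csf1r (20825 CPM), the adhesion ligand gene Selplg (6633), the protease gene Ctsz (1737), the antigen-loading gene Tapbp (640), the transcription factor gene Stat6 (397) and the chaperone genes Hspa5 (1246) and Hsp90b1 (1210).

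In saline 1 the neuronal and astrocyte transcripts were nearly missing, with a median log2 deviation of -3.94 over 21 markers. Other genes of the same range of expression had a median log2 deviation of -0.0096 there, which cannot decide on depth, since CPM is already scaled to library size. Lower depth is argued against by the library totals. Saline 1 held 18476279 counts, while ethanol 1, ethanol 3 and saline 4 held fewer (12816198, 17877881 and 18016777). These had 39.8, 50.7 and 49.5 CPM of summed neuronal markers. The age of the mouse is argued against by the other 3 older mice, whose markers differed from the younger mice by a median log2 of -0.21. This is a difference of mean log2 CPM without the ethanol term. The medians of the age fit without saline 1, given above, were larger in size but well short of -3.94. In the other 8 libraries the markers rose and fell together, with a mean pairwise r of 0.428 across libraries, above all of 10000 random lists of like expression (percentile 100, median r of these 0.0079), as would be seen if RNA of neurons and astrocytes was carried along through the sort in amounts that differed from mouse to mouse, so a cleaner sort of saline 1 is a candidate explanation. Saline 1 also carried neither of the library-name suffixes of the other mice. It had the fewest sorted cells (8923), cells per mg (198) and detected genes (16835) of all libraries. What the suffix stands for is not known, so separate handling of saline 1 cannot be told apart from the mouse. Not all other marker sums were low in saline 1. Those of endothelial cells and pericytes (72.9 CPM), border macrophages (68.0 CPM) and lymphocytes (49.6 CPM) lay above the saline mean. Of their listed markers only 3 of 12, 4 of 10 and 1 of 10 passed the count filter. The border macrophage sum was nearly all Mrc1 and the lymphocyte sum nearly all Cd79b. Sums that rest on so few genes cannot decide how clean the sort was. Monocyte and neutrophil markers (6.38 CPM) lay below it, and oligodendrocyte (198 CPM) and erythroid markers (0.560 CPM) were the lowest of all libraries. The weight of the tissue of saline 1 (45 mg) is argued against as a source, since the 6 lighter and 2 heavier mice all had at least 31.9 CPM of summed neuronal markers, against 5.99 CPM in saline 1.

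In ethanol 2, Tgfb1 was lowest of the ethanol mice (43.0 CPM, others at least 248) and Msmo1, of cholesterol synthesis, was highest (60.1 CPM, others at most 44.0). Tgfb1 belongs to the 695 genes more than 2-fold low in that library. Exposure to ethanol as the source is argued against by the other 3 ethanol mice, in which the same genes differed from saline mice by a median log2 of -0.013, and RNA integrity by the 3 other libraries with an integrity number no higher, where the lowest median deviation of these genes was -0.041. Loss of reads from long transcripts may account for part of it: across genes, which are not independent replicates, the deviation fell with transcript length with a Spearman correlation of -0.53, against -0.23 to 0.20 in the other libraries. A smooth trend on annotated length and GC content was not the whole source, since 277 such genes were left after it was removed, against at most 40 in another library, and the median log2 deviation of all 695 went from -1.37 to -0.87.

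The other distances past the limit were single values, each compared within its own treatment group. The library total of saline 2 was highest of the saline mice, at 28.9 M counts. Il6 was lowest of the saline mice in saline 2 (5.89 CPM) and B2m lowest of the ethanol mice in ethanol 4 (1577 CPM). Of the ethanol mice, ethanol 4 was highest for summed oligodendrocyte markers (264 CPM), Slc17a7 (12.4 CPM), Mbp (123 CPM) and Cbr2 (0.938 CPM). Ethanol 3 was highest of the ethanol mice for summed border macrophage markers (92.1 CPM), Mrc1 (89.0 CPM), Mag (31.5 CPM) and the chemokine receptor gene Ccr2 (15.8 CPM). Nfkbia (150 CPM) and Hba-a1 (0.491 CPM) were, among the saline mice, highest in saline 3.

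In the test of the interaction itself, a pair of gene lists passed by camera with the preset correlation. These were the immediate early and dissociation response (adjusted p = 0.00503) and astrocyte markers (4.5e-05). Other splits of the mice were not tried for the interaction, so chance cannot be excluded. Saline 1, 1 of the 2 older saline mice, had a mean log2(CPM + 1) of astrocyte markers of 1.17, against 3.09 in saline 3. Neither list passed with an estimated correlation (adjusted p = 0.979) or by fry (adjusted p = 0.962). Without both saline 1 and ethanol 2 neither passed with the preset correlation, nor did astrocytes without saline 1 alone. These fits leave a single mouse in 1 or both of the older arms, so the lost calls decide nothing. Both lists stayed on the higher side in them.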

How the results depend on the processing

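The tests of other splits, leaving out both saline 1 and ethanol 2, leaving out each library with an estimated correlation, and removing the trend on GC content and length were chosen only after the data had been seen. For ethanol against saline, 0 genes passed in edgeR's test (386 under the unadjusted threshold) and in all 24 alternatives (DESeq2 578 and limma-voom 505 under it). With 100 of the 126 splits of the 9 mice drawn, 55 gave as many lists (real 4, highest other 12), so chance cannot be excluded for these lists; for genes the count of 100 splits decides nothing, since any split reaches a real value of 0 (highest other 1). Leaving out each library gave 2 to 7 lists, and 0 passed with an estimated correlation or by fry of either kind; with both an estimated correlation and each library left out 0 or 1 did for ethanol and 0 for age. The adjusted p over 18 alternatives ran from 5.2e-10 to 0.730 for astrocytes, 2.3e-05 to 0.730 for neurons, 1.3e-07 to 0.730 for border macrophages and 1.2e-05 to 0.730 for cytokines. Without both libraries it was 0.166 for neurons and 0.0460 for astrocytes. The replicate numbers do not pair the mice (correlations of deviations -0.016, -0.010, -0.054 and -0.014, no library correlating best with its own number); with the number as a block 0 genes and 8 lists passed for ethanol and 0 genes for age. For age, 20 of 23 alternatives gave 0 genes; 97 passed without a count filter (16 higher, 81 lower, 88 of them also tested with the filter), 1 with DESeq2, and 3 without both libraries. For age lists the values were 1 to 8 leaving out each library, 0 with an estimated correlation or by fry of either kind, and 2 without both libraries, where homeostatic microglia reversed (adjusted p = 0.786). Of 100 splits, 30 gave as many lists for age (real 6, highest other 14), so chance cannot be excluded for these either; the count of 100 for genes again decides nothing (real 0, highest other 0). For the interaction, 10 of 13 alternatives gave 0 genes, 53 passed without a filter, 1 with DESeq2, and leaving out each library gave 0 to 848; the 848 came without ethanol 1, where ethanol 2 alone stood for the older ethanol mice and was assumed to vary like the other groups. Of 552 fold changes of the 37 named genes in settings that keep or drop more than single libraries, 537 kept their direction and their side of the threshold and 15 reversed, each with a log2 fold change close to 0: with limma-voom Mcm3 (-0.015) and Scd2 (0.024), with a surrogate variable Irf8 (-0.0034), without both libraries Mcm3 (-0.013) and Scd2 (0.054), with the GC and length trend removed Scd2 (0.014), with the replicate block Cst3 (-0.020) and Irf8 (-0.0069), in older mice alone Cst3 (-0.0048), Irf8 (-0.10) and Mcm6 (0.028), in younger mice alone Ctsd (-0.015) and Mcm3 (-0.0050), and with sorted cells as a covariate Cst3 (-0.0041) and Irf8 (-0.012). Leaving out each library, 318 of 330 did not reverse; the log2 fold change ran from -0.0067 to 0.13 for C1qb, -0.021 to 0.081 for Cst3, -0.015 to 0.14 for Ctsd, -0.048 to 0.057 for Irf8, -0.064 to 0.089 for Mcm3, -0.082 to 0.013 for Ncf1 and -0.13 to 0.044 for Scd2. A further 12 of the 37 genes kept their sign but moved by over 1.5 times without at least 1 library, 8 of them without ethanol 2. Cells per mg ran from -9.55 to 58.6 and the RNA integrity number from -0.15 to 0.127 (ethanol minus saline), and monocyte and neutrophil markers reversed on the scale of mean log2 CPM (-0.035). None of the 8 recorded measures or 8 marker sums passed in any alternative. Of the list tests in alternatives, 343 of 414 for ethanol and 318 of 391 for age were on the same side in the same direction. The cause of these changes was not tested. Of genes under 1 CPM, 5.85% had an interval within 2-fold. Counting error and variation between libraries were not separated there.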

Other observations

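All tests in this part, and the genes named, were chosen only after the values had been seen. Tagap and Nfkbia separated the mice in a way that the age cohorts did not. The 3 mice aged 35 days (saline 3, ethanol 1 and ethanol 2) had 204, 200 and 157 CPM of Tagap and 150, 180 and 164 CPM of Nfkbia. The mouse aged 36 days, saline 1, had 99.5 and 100 CPM, within the range of the younger mice (91.3 to 113 CPM of Tagap and 87.3 to 110 CPM of Nfkbia). Adrb1 was at 83.0 and 62.9 CPM in saline 3 and ethanol 1 and at 16.2 CPM in ethanol 2, against 38.9 to 47.8 CPM in the rest. The 3 mice of 35 days carried the same suffix in their library names as saline 4, aged 29 days, which had 112 CPM of Tagap and 95.8 CPM of Nfkbia. Between the suffixes, with ethanol as a covariate and saline 1 left out, 0 of 13001 genes passed in edgeR's test, with 994 under the unadjusted threshold where chance gives 650; no other tool was run on this comparison. Of the 34 splits of these 8 mice into 4 and 4 that the test allows, 5 gave as many under it, the suffixes included (highest other 1649), so chance cannot be excluded; the other splits that did so each set ethanol 2 apart from the other 3 ethanol mice.

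Ethanol 2 had the highest CPM of the chemokine genes Ccl3 (44.4, others 10.9 to 28.6) and Ccl4 (51.6, others 17.8 to 39.5) and of the interferon-induced genes Usp18 (17.8, others 5.39 to 11.1) and Rtp4 (41.9, others 12.2 to 26.0). These values come from 1 mouse and were not tested.

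Genes known to be induced by glucocorticoids, the stress and circadian hormones of the adrenal cortex, differed many-fold between mice: Ddit4 ranged from 2.93 to 122 CPM, Tsc22d3 from 46.2 to 412 CPM, Fkbp5 from 75.6 to 433 CPM and the clock gene Per1 from 5.80 to 67.6 CPM, with a mean log2 CPM of the 4 genes highest in saline 3 (7.58) and ethanol 1 (7.08) and lowest in saline 2 (4.13), saline 1 (4.81) and ethanol 2 (5.11). Exposure to ethanol, the age cohort and the library-name suffix are each argued against as the source of the whole spread by the log2 range of this mean among the saline mice (3.45), the younger mice (2.71) and the 4 mice of the suffix without saline 1 and ethanol 2 (1.97), while a part stays open for each (exact two-sided permutation p = 0.976 for ethanol minus saline, log2 difference -0.04; 0.532 for older minus younger, 0.49; 0.114 for the suffixes, 1.29, 4 against 4 mice). Glucocorticoid signalling was first tested on a whole glucocorticoid-induced list of 17 genes (mean pairwise r 0.14, percentile 99.3 of 10000 random lists of like expression), which holds the 4 genes, then on its 13 other members (mean r of 0.22 with the 4 genes, 9 of 13 positive, percentile 98.4), and only after that result on the 9 of these on no list fixed beforehand (mean r 0.07, 5 of 9 positive, percentile 68.7). The remaining 4 of the 13, each also on a list fixed beforehand, had a mean r of 0.555 (4 of 4 positive, percentile 99.9). Of the 13, Cebpb had the highest r (0.778), followed by Rhob (0.705), Dusp1 (0.545), Zfp36 (0.503), Nfkbia (0.468), Sgk1 (0.461) and Mt1 (0.445), while Errfi1 (-0.577), Bcl6 (-0.519), Cebpd (-0.385) and Cdkn1a (-0.151) were negative. Rhob, Dusp1 and Zfp36 also belong to the immediate early and dissociation response, whose 19 other members had a mean r of 0.11 (12 of 19 positive, percentile 90.0), so both glucocorticoid signalling and a response to the dissociation of the tissue stay open.

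The levels of neural transcripts were also compared with the weight of the dissected tissue, a relation that did not pass. Over the 9 mice the mean log2(CPM + 1) of neuronal markers had a Pearson r of 0.159 with tissue weight (exact permutation p = 0.707; Spearman rho 0.483, exact p = 0.194; r of 0.270 without the 2 mice farthest from the median weight). Astrocyte markers had an r of 0.0632 (exact p = 0.881; rho 0.317, exact p = 0.410; 0.259 without the 2 farthest) and oligodendrocyte markers one of 0.197 (exact p = 0.625; rho 0.400, exact p = 0.291; 0.296). Over the 8 mice other than saline 1, neuronal markers had an r of 0.793 (exact p = 0.0161; rho 0.762, exact p = 0.0368; r of 0.571 without the 2 farthest), astrocyte markers one of 0.593 (exact p = 0.125; rho 0.524, exact p = 0.197; 0.769) and oligodendrocyte markers one of 0.693 (exact p = 0.0638; rho 0.643, exact p = 0.0962; 0.713). Adjusted over these 6 relations the smallest p was 0.0964 for Pearson and 0.221 for Spearman.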
